A study of Mus musculus with 2 samples.

How the data were processed

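Single cells from mouse testis, 1 library from mice aged 2 months and 1 from mice aged 24 months, were measured by RNA sequencing on the BD Rhapsody system. Per the submitters' protocol notes, the tunica was removed, the tissue was minced and digested with accutase, and the suspension was passed through a strainer. The labels call the cells stroma cells, while most cells in the files carry germ cell markers. The authors deposited whole-number counts per gene and cell, 1 table per library, with no normalization. The aged table carries a header that names version 1.7.1 of the BD Rhapsody pipeline and STAR 2.5.2b, the young table has no header, and the submitters' processing notes name Cell Ranger 2.11 and the mm10 genome (GRCm38). The sources differ on the pipeline, and neither says how cells were called or whether a count is a molecule or a read. The lowest total of a cell was 3215 in the young and 186 in the aged table, and the reason for this gap is not stated. The young table held 2771 cells and 40184 gene columns with a median of 16582 counts per cell, and the table of the aged library held 6823 cells and 39087 gene columns with a median of 7488. The tables share 36245 gene columns, and a gene absent from a table was taken as 0 there. Of 41061 genes with a count, 98.4% were found by name in the GENCODE M21 annotation, which gave the coordinates.

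Cells with 500 or more counts, 200 or more genes and at most 25% mitochondrially encoded counts were kept, which left 2770 young and 5812 aged cells. Of the aged cells removed, 311 were low in counts or genes and 700 high in mitochondrially encoded counts. Scrublet, as run in scanpy 1.11.5 on each library, called 38 young (1.37%) and 121 aged (2.08%) cells doublets, and these were removed. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 40 principal components were taken, and cells of both libraries were clustered together without batch correction on a graph of 15 neighbours (leidenalg 0.10.2, resolution 1, seed 1). Clusters were named from marker lists by the mean z-score of detected markers, with at least 3 markers up and a mean of 0.5, and left unnamed where the best classes lay within 0.15, where another class also scored over 1.5, where depth was under 1 part in 3 of the library median with fewer than 2 own markers among the 10 leading genes, or where markers lay more than 2 log2 units under another cluster of the class. The limits for mixed, shallow and distant clusters were set after the clusters had been seen. They leave 9.99% of young and 26.1% of aged cells unnamed. With classes from each cell's own marker score, 36 of 2732 young and 396 of 5691 aged cells lay within 0.1 of the limit.

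Counts were summed over the cells of a class in a library and given as CPM, counts per 1000000 of that sum, with exact Poisson 95% intervals. Ratios carry exact conditional binomial intervals and shares exact Clopper-Pearson intervals. With 1 library per age no p-value, standard error or count of changed genes was made. Log2 ratios used 0.5 added to each count. Classes with at least 50 cells in each library were compared, which are the Leydig-like, spermatocyte-like, round spermatid-like and elongating spermatid-like cells. For 29 gene lists, the median log2 ratio of members with 10 or more counts (at least 5 such members) was placed among 10000 random lists of the same size matched in 20 bins of expression. Members at least 1.5-fold higher or lower are counted by size alone. List medians under the alternatives were set against intervals from 1000 Poisson draws.

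The comparisons, marker lists, gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. By that rule the text names, per class, the 6 genes with the highest and the 6 with the lowest ratio among genes with 50 or more counts, 50 or more CPM where higher, and at least 0.5 times the level outside the class there, leaving out gene models, mitochondrially encoded, ribosomal and globin genes. For lists it names the 2 members furthest from equality and the 2 most abundant, of which the text gives a part. This was narrowed after values and alternatives had been seen: members named have at least 10 CPM in a library, and in germ cells members of only 9 lists are named. Klk1 family sums, Aldh1l1 and Osbpl1a across classes, and detection after thinning were chosen after values had been seen. Macrophage-like and fibroblast-like cells fell under 50 young cells and are described apart.

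Alternatives to the cell filter, doublet removal, clustering resolution, class naming, depth, scaling, free RNA, averaging and list minimum were run 1 at a time. Lower cell totals in both libraries and single clusters were added after the data had been seen. A gene with fewer than 10 counts under an alternative got no value there. The intervals and lists were tested on simulated data with the depths of these libraries. The 95% interval of the ratio held the true value for 96.0% of 11088 genes in Leydig-like, 95.4% in spermatocyte-like, 95.7% in round spermatid-like and 96.2% in elongating spermatid-like cells. Of 200 lists drawn at random without a difference, 8.5% lay outside their random lists in the round spermatid-like cells. In the Leydig-like, spermatocyte-like and elongating spermatid-like cells 6% or fewer did. A list set 1 log2 unit higher lay at the 100th percentile in each class. Single genes set 1 log2 unit higher had a median estimate of 0.97 to 1.00, and those set 2 units lower of -2.04 to -1.86. The simulated counts were independent Poisson draws from 1 profile. These rates therefore do not cover list members that vary together, or cells that differ within a class. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 were used. Median counts per cell were 6937 and 4754 in young and aged Leydig-like cells, 30668 and 16875 in spermatocyte-like cells, 29077 and 16538.5 in round spermatid-like cells and 19511 and 11532 in elongating spermatid-like cells. Of the aged cells, 1597 lay under the lowest total of the young table. No free RNA correction was made in the values reported.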

Results

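Cells of the mouse testis were measured by single-cell RNA sequencing in 2 libraries, 1 from mice aged 2 months (young) and 1 from mice aged 24 months (aged). The labels do not say how many mice gave each library. The question set by the study's title is how gene expression in testicular cells differs between the ages. The young file held 2771 cells with 53413783 counts in all, and the aged file 6823 cells with 66390904 counts. After filtering and removal of called doublets, 2732 young and 5691 aged cells were analysed, with a median of 15649.5 and 11381 counts and of 4035 and 4038 genes per cell. With 1 library per age no difference has a replicate check and no test was possible. Values are given with exact 95% intervals, Poisson for levels, conditional binomial for ratios and Clopper-Pearson for shares, which cover counting error only. Levels are given as CPM, the counts of a gene per 1000000 counts summed over the cells of a class in a library. Ratios are aged over young.

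Leydig-like cells, the androgen-producing cells that lie between the seminiferous tubules, made up 39.9% of the young cells (95% interval 38.1 to 41.8) and 10.2% of the aged cells (9.43 to 11.0). Spermatocyte-like cells, the germ cells in meiosis, made up 24.0% of the young cells (22.4 to 25.6) and 41.0% of the aged cells (39.7 to 42.3). Round spermatid-like cells made up 19.9% and 14.8%, and elongating spermatid-like cells 4.14% and 2.78%. Macrophage-like cells were at 1.46% and 1.56%, and stromal fibroblast-like cells at 0.622% (17 cells) and 2.28% (130 cells). Spermatogonia-like cells, which precede meiosis, formed a cluster of 76 aged cells (1.34%) and 0 of 2732 young cells, which allows a share of up to 0.135%. Their median of 2332 counts lies under the lowest total of any cell in the young file, 3215. A cluster that holds cells of 1 library may be that library and not a type.

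**Figure D1:**
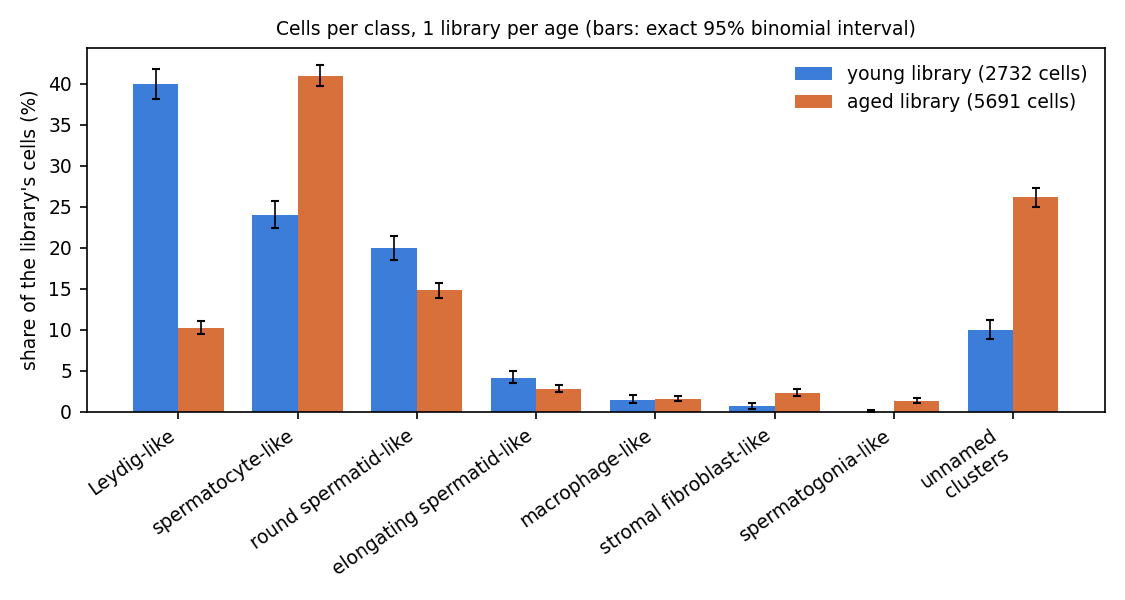
Share of each library's cells (vertical axis, percent) in each class, young in blue and aged in orange, with exact 95% binomial intervals as thin bars. Leydig-like cells stand at 39.9% and 10.2%, and spermatocyte-like cells at 24.0% and 41.0%.

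Among spermatocyte-like and spermatid-like cells alone (1312 young, 3329 aged), spermatocytes were 49.9% of the young and 70.0% of the aged cells, round spermatids 41.5% and 25.2%, and elongating spermatids 8.61% and 4.75%. The ratio of this elongating share ran from 0.660 to 1.18 over 5 alternatives and lay above 1 in 1 of them. Among the named somatic cells (1147 young, 800 aged), Leydig-like cells were 1090 (95.03%) and 581 (72.6%). Macrophage-like cells were 3.49% and 11.1% of them, and fibroblast-like cells 1.48% and 16.3%. These shares leave out unnamed cluster 21 (88 young, 0 aged cells), which scored highest for macrophage markers. Leydig-like cells per macrophage-like cell were 27.25 and 6.53 without that cluster, and 8.52 and 6.53 with it. The macrophage shares among somatic cells therefore turn on that cluster. Unnamed clusters held 9.99% of the young and 26.1% of the aged cells. Of these, cluster 6 (0 young, 506 aged cells) scored highest for spermatocytes. Cluster 7 (2 and 424) scored highest for round spermatids and cluster 10 (75 and 310) for elongating spermatids. The shares among spermatocyte-like and spermatid-like cells leave these clusters out, so they depend on which clusters were named. The libraries differed in depth, with a median of 30668 counts per young and 16875 per aged spermatocyte-like cell and no young cell under 3215 counts while 28.1% of the aged cells lay under that total. Among all cells the elongating spermatid ratio turned above 1 in 8 of 9 alternatives, and the macrophage ratio of 1.07 went down to 0.220. With the lowest total of the young file applied to both libraries the round spermatid ratio was 1.04 and the fibroblast ratio 0.236. The Leydig ratio stayed between 0.205 and 0.299 in all 9.

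Within Leydig-like cells (1090 young, 581 aged), the genes with the highest aged to young ratios included a chemokine gene and an acute-phase gene, and those with the lowest were mostly of the kallikrein family. Ccl2, a chemokine that draws monocytes (GRCm38 chromosome 11, 82035571 to 82037453), was at 2.02 CPM in the young and 100.2 CPM in the aged library, a ratio of 49.7 (30.1 to 88.2). Saa3, an acute-phase serum amyloid gene, was at 1.26 and 55.8 CPM (ratio 44.3, 23.4 to 94.1). Fetub, of the fetuin family of protease inhibitors, was at 20.7 and 313 CPM. The histone gene Hist1h4h was at 5.80 and 81.0, the serine/threonine kinase gene Pim1 at 41.2 and 377, and the surface protein gene Ly6d at 25.7 and 211. These 6 genes had the highest ratios under the naming rule.

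Of the 6 lowest, 5 were kallikrein genes, which code for secreted serine proteases. Klk1b22 was at 270.1 CPM in the young and 17.8 in the aged library, 15.2-fold lower (11.5 to 20.6). Klk1b27 (chromosome 7, 44052290 to 44056712) was at 998 and 75.3 CPM, Klk1b21 at 1407 and 136, Klk1b24 (chromosome 7, 44188236 to 44192455) at 951 and 135, and Klk1b16 at 186 and 40.9. The kallikrein genes lie side by side and are near copies of each other, so reads can pass between them and the level of any single member is uncertain. Summed over the 12 measured Klk1 and Klk1b genes, the level was 3905 CPM in the young and 469 CPM in the aged library, with 11 members at least 1.5-fold lower and Klk1 2.80-fold higher. Klk1b21, Klk1b24, Cyp17a1 and Hsd3b6 were also among the markers used to name the class. Gpx8, a glutathione peroxidase of the endoplasmic reticulum, was at 50.9 and 5.68 CPM. Klk1b27 had a count in 85.1% of young and 19.3% of aged Leydig-like cells, and in 66.5% and 11.4% once each cell was thinned to 2000 counts (0 young and 53 aged cells left out as shallower). Median depths there were 6937 and 4754 counts. In spermatocyte-like cells, at 30668 and 16875 counts, the share was 5.34% and 0.129%, and 0.458% and 0% after thinning.

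**Figure D2:**
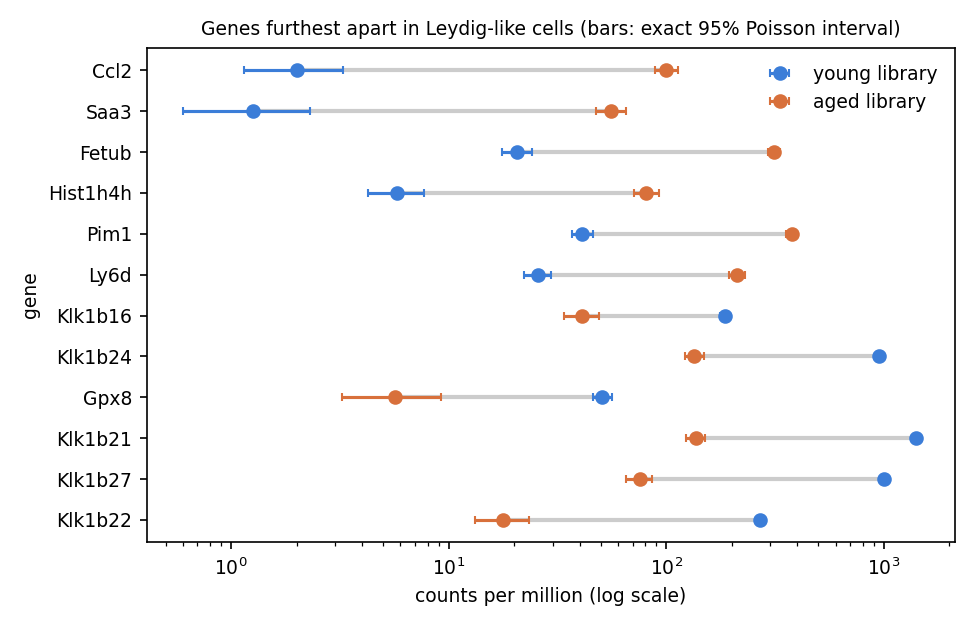
Level of the 12 genes furthest apart in Leydig-like cells (horizontal axis, CPM, log scale), young in blue and aged in orange, with exact 95% Poisson intervals. Ccl2 lies at 2.02 and 100.2, and Klk1b22 at 270.1 and 17.8.

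For gene lists fixed beforehand, the median log2 ratio of a list's measured members was placed among 10000 random lists of the same size and expression, and this percentile describes these libraries only. In Leydig-like cells 13 of 26 measured lists lay outside the central 95% of their random lists, 10 above and 3 below. Steroidogenesis, the making of androgens from cholesterol, lay inside it at -0.10 (12.4th percentile), with 0 of 18 members at least 1.5-fold higher and 2 lower. Its most abundant members were Cyp17a1 (chromosome 19, 46667165 to 46673172), the hydroxylase and lyase that forms androgen precursors, at 10518 and 6599.8 CPM (ratio 0.627, 0.618 to 0.638), and Hsd3b6, a hydroxysteroid dehydrogenase of adult Leydig cells, at 3891 and 2979 CPM. Srd5a1, a steroid reductase, was at 24.1 and 8.53 CPM. Not every member was lower. Star of the same list, which the naming rule does not pick, was at 1879 and 2121 CPM (ratio 1.13, 1.09 to 1.16). Genes of cholesterol synthesis had a median of 0.51 (100th percentile), with 9 of 21 members higher and 0 lower by that size. Examples are Hmgcs1, which makes a precursor of mevalonate, at 329 and 596 CPM (1.81-fold) and the sterol-regulated Insig1 at 87.8 and 168. The abundant demethylase gene Cyp51, at 478 and 682, was higher by less than 1.5-fold.

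Several immune lists were also above their random lists in Leydig-like cells, while complement lay inside them (-0.18, 10.9th percentile, 1 of 11 higher, 2 lower). Senescence and secreted factors had a median of 2.15 (100th percentile), with 9 of 15 members higher and 1 lower, and of 1.04 over the members with 50 counts or more (5 of 10 higher, 1 lower). The neutrophil chemokine genes Cxcl1 (390.2 and 1456 CPM, ratio 3.73, 3.56 to 3.91) and Cxcl2 (0.378 and 17.1 CPM) were higher in the aged library, and Igfbp7, which binds insulin-like growth factors, was at 2609 and 1728 CPM. The inflammatory macrophage list, which shares Ccl2, Cxcl1 and Cxcl2 with it, had a median of 2.22 (100th percentile, 6 of 8 higher, 1 lower). Interferon response genes had a median of 0.80 (100th percentile), with 12 of 20 higher and 0 lower, among them the GTPase genes Iigp1 (41.3 and 128 CPM) and Gbp2 (7.43 and 24.5) and the antiviral Rsad2 (6.05 and 27.0). The abundant Bst2 was at 186 and 201. MHC class I genes, which present peptides on most cells, had a median of 0.29 (99.9th percentile, 4 of 15 higher, 0 lower), with H2-K1 at 748 and 1014 CPM and B2m at 1542 and 1793. MHC class II genes, which mark antigen-presenting cells, had a median of 2.39 (100th percentile, 4 of 5 higher, 0 lower) at low levels, with Cd74 at 1.89 and 13.9 CPM and H2-Aa at 2.27 and 12.1. The macrophage gene Lyz2 was at 12.85 and 20.96 CPM in the same cells (ratio 1.63, 1.16 to 2.27) and C1qb at 10.7 and 12.1. The endothelial function list had a median of 0.77 (100th percentile, 5 of 8 higher, 0 lower), among them the adhesion gene Icam1 (23.3 and 99.5 CPM) and the transcription factor gene Klf2 (110.4 and 338), which other cells also express. With members of 1 count or more it was 0.32, inside its random lists. The endothelial function list shares Klf2 and Klf4 with the dissociation and stress list described below.

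DNA damage response genes had a median of 0.27 (99.5th percentile, 6 of 18 higher, 2 lower). The cell cycle inhibitor gene Cdkn1a, also on the senescence and secreted factors list, was at 35.7 and 159 CPM (ratio 4.45, 3.83 to 5.19). The stress gene Gadd45b was at 6.17 and 48.7. The cell cycle list had a median of 0.35 (98.7th percentile, 6 of 17 higher, 3 lower), with Mcm4 at 9.57 and 17.8 CPM and Pcna at 42.6 and 54.0. Dissociation and stress genes, which respond to tissue handling, had a median of 0.43 (100th percentile, 8 of 22 higher, 0 lower), with Klf6 at 108 and 370.2 CPM, Fos at 1581 and 1836 and Jun at 1330.3 and 1678. Ribosomal protein genes had a median of -0.22 (0th percentile), with 0 of 77 higher and 1 lower, and Rplp0 was at 417 and 280.3 CPM. The resident macrophage list (0.31, 93.6th percentile, 3 of 8 higher, 0 lower) and the Sertoli function list (-0.18, 4.43th percentile, 1 of 16 higher, 7 lower) lay inside their random lists, with Gas6 at 192 and 232 CPM and Gja1 at 219.7 and 326. Spermatid transcripts measure free RNA in these cells, and their chromatin compaction list (-1.16, 0th percentile, 1 of 11 higher, 7 lower) and sperm motility list (-0.34, 0th percentile, 0 of 24 higher, 7 lower) were lower in the aged library. Prm1, Prm2, Tnp1 and Tnp2 together were at 790 CPM in young and 276 CPM in aged Leydig-like cells, which is 11.2% and 6.43% of their level in the whole library.

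**Figure D3:**
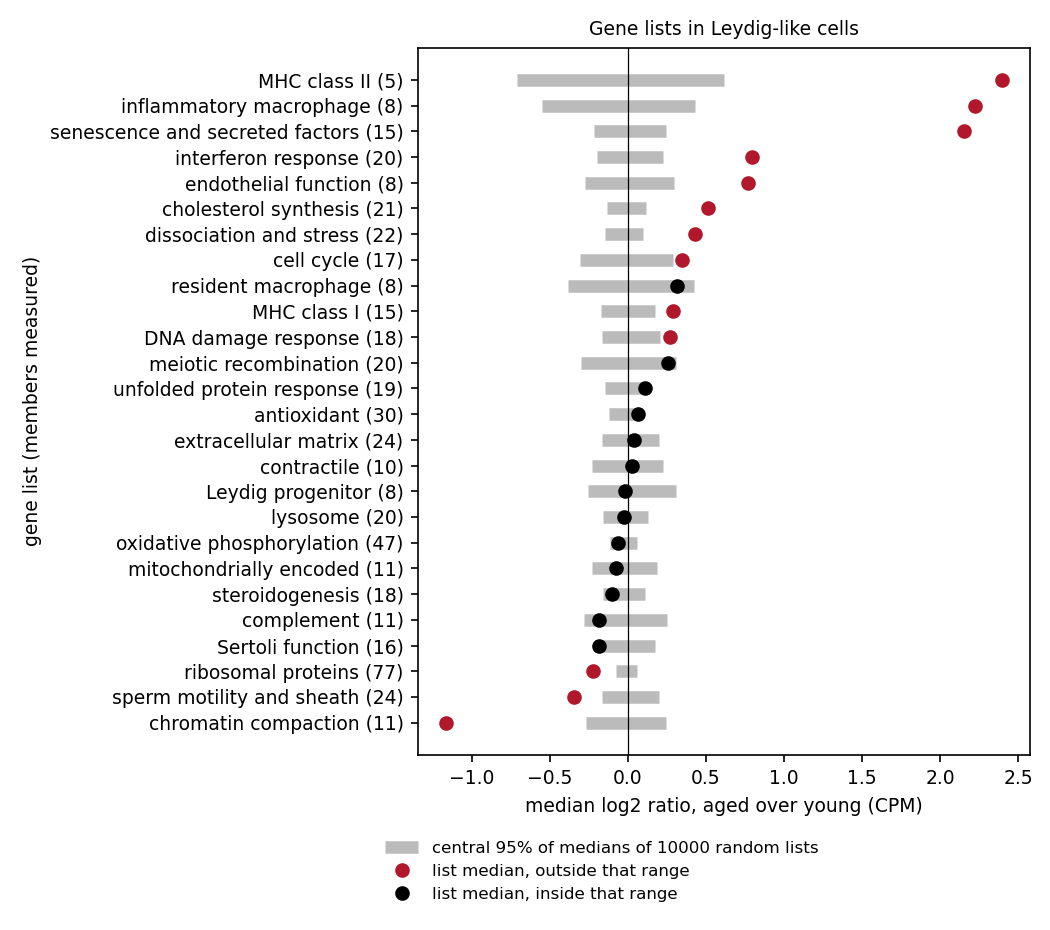
Median log2 ratio, aged over young, of each gene list in Leydig-like cells (horizontal axis), with the number of measured members beside its name. Grey bars span the central 95% of 10000 random lists and red points lie outside them, with MHC class II at 2.39 the highest and chromatin compaction at -1.16 the lowest.

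The Leydig-like cells of the libraries lay mostly in different clusters. There were 1049 young and 57 aged cells in cluster 2, led by Klk1b21, Klk1b27 and Cyp17a1, and 41 young and 524 aged cells in cluster 4, led by Bhmt, Agt, Cxcl1 and Fetub. Within cluster 2 alone, an alternative chosen after the data were seen, the medians were -0.22 for senescence and secreted factors, -0.27 for DNA damage response, -0.016 for cell cycle and 0.015 for MHC class I (29.0th percentile), with B2m at -0.14. The 57 aged cells hold 261875 counts, so that low genes there rest on few counts, with 5 for Ly6d (log2 ratio -0.34), 2 for Cdkn1a (-1.89), 1 for Ccl2 and 0 for Cd74 and H2-Aa. In cluster 4 alone the ribosomal protein median was 0.30, cell cycle -0.038 and cholesterol synthesis 0.18. Senescence and secreted factors stayed high there at 1.67 (8 of 13 higher, 0 lower). In clusters 2 and 4 alone the log2 ratios of Klk1b27 (-2.69 and -1.19) and Cyp17a1 (-0.60 and -0.63) and the interferon median (0.84 and 0.85) kept their direction. Several of the largest ratios of the class were nearer to equality within each cluster. The clusters were made from these same cells and are led by some of these genes, such as Klk1b21 and Fetub. Values nearer to equality within them therefore do not separate a difference between ages from one between clusters. Ccl2 went from 5.59 to 1.61 and 3.36 (2 young counts in cluster 4). Fetub went from 3.92 to 2.37 and 2.42, and Pim1 from 3.19 to 2.01 and 2.32. Klk1b22 went from -3.91 to -3.48 and -1.38, and Klk1b21 from -3.37 to -2.19 and -1.38. Gpx8 went from -3.12 to -1.61 and -0.40. In cluster 4 Gpx8 was at 4.31 CPM in the young and 4.70 CPM in the aged library. Its negative log2 ratio there comes from the constant added to each count, so it gives no direction. Ly6d, Saa3 and Hist1h4h had 0 young counts in cluster 4, against 231, 61.5 and 82.3 CPM in the aged library. With classes taken from the marker score of each cell, the MHC class II median was -0.075, and with doublets kept the sperm motility median was 0.045.

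Aldh1l1, which codes for a folate dehydrogenase (GRCm38 chromosome 6, plus strand, 90486427 to 90600203), was the gene furthest apart in spermatocyte-like cells (655 young, 2331 aged). It had 1884 counts there in the young library (88.4 CPM, 84.5 to 92.5) and 9 counts in the aged library (0.227 CPM, 0.104 to 0.432), 389-fold lower (204 to 851). In round spermatid-like cells it was at 83.0 and 2.43 CPM, 34.1-fold lower (24.3 to 49.5). Of 3828 genes at 50 CPM or more in young spermatocyte-like cells, it was the only 1 under 0.1 times that level in the aged library, and the next lowest ratio was 0.339. Its level in other classes was looked up after these values were seen. In elongating spermatid-like cells it was at 47.7 and 5.17 CPM, and in Leydig-like cells at 427 and 422 CPM, a ratio of 0.989 (0.925 to 1.06). A count was found in 47.2% of young and 0.386% of aged spermatocyte-like cells, at median depths of 30668 and 16875 counts, and in 14.5% and 0.0450% of cells thinned to 2000 counts (0 young and 108 aged cells left out). In macrophage-like cells, with median depths of 4447.5 and 1866 counts, a count was found in 7.5% and 1.12%.

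**Figure D4:**
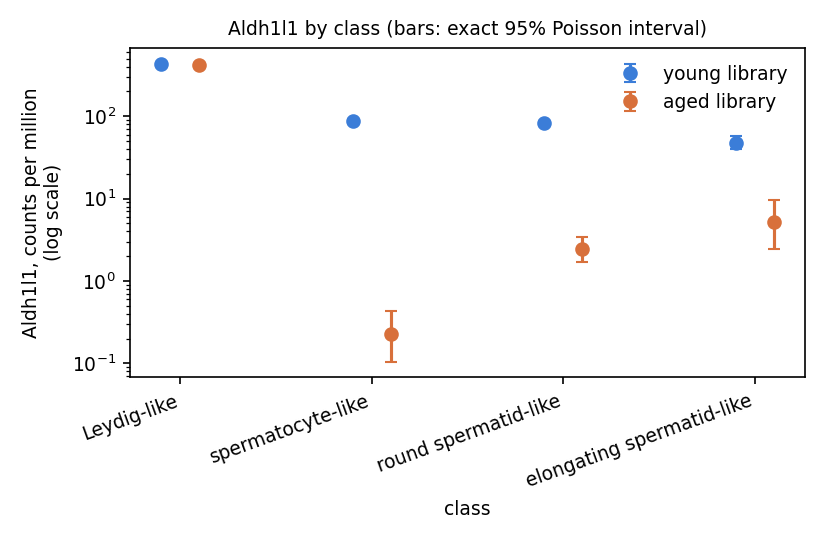
Level of Aldh1l1 in 4 classes (vertical axis, CPM, log scale), young in blue and aged in orange, with exact 95% Poisson intervals. Leydig-like cells lie at 427 and 422, and spermatocyte-like cells at 88.4 and 0.227.

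Osbpl1a, of the oxysterol-binding family (chromosome 18, 12755314 to 12941841), was also lower in aged spermatocyte-like cells, at 157 and 53.1 CPM (2.95-fold, 2.79 to 3.11). So were the cyclin gene Ccnb1 at 149 and 77.4, Camk2n2, an inhibitor of a calmodulin-dependent kinase, at 51.3 and 26.7, Rhno1 at 77.3 and 42.0, and Elfn1 at 87.3 and 50.4. Higher were Adad2, a testis RNA-binding protein gene, at 17.7 and 60.9 CPM (ratio 3.44, 3.09 to 3.85), the splicing factor gene Rnps1 at 20.1 and 52.8, and the Polycomb gene Pcgf5 at 44.6 and 112. Tdrd5, which takes part in the silencing of transposons, was at 66.4 and 165, the chromatin protein gene Hmgb2 at 53.4 and 129.7, and Fbxo3 at 29.3 and 68.5. Adad2 and Pcgf5 are among the leading genes of cluster 8, which holds 18 of the 655 young and 392 of the 2331 aged cells of the class. Within cluster 1 alone the log2 ratio was 0.47 for Adad2, 0.31 for Rnps1, 0.25 for Pcgf5, 0.26 for Tdrd5 and 0.058 for Hmgb2.

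In spermatocyte-like cells 13 of 29 lists lay outside their random lists, 6 above and 7 below. Meiotic recombination genes had a median of 0.36 (99.9th percentile), with 7 of 22 members at least 1.5-fold higher and 0 lower. Examples are the crossover helicase gene Hfm1 at 14.9 and 38.7 CPM (ratio 2.59, 2.30 to 2.93) and Sycp2 of the synaptonemal complex at 313 and 521, while Syce1 of the same complex was at 922 and 881. DNA damage response genes had a median of 0.44 (99.8th percentile, 6 of 19 higher, 2 lower), with the checkpoint kinase gene Atr at 327 and 387 CPM. Spermatogonial differentiation genes had a median of 0.69 (99.6th percentile, 6 of 9 higher, 1 lower), while the abundant Dmrtb1 was at 1478 and 1279 CPM. Genes of energy metabolism and translation were higher by small amounts, with medians of 0.17 for oxidative phosphorylation (100th percentile, 4 of 47 higher, 1 lower), 0.22 for mitochondrially encoded genes (98.05th percentile, 2 of 11 higher, 0 lower) and 0.26 for ribosomal proteins (100th percentile, 1 of 77 higher, 4 lower). Atp5g3 of the ATP synthase was at 96.1 and 180.5 CPM, the cytochrome gene mt-Cytb at 745 and 1394, and Rpl10a at 7.18 and 16.2. The abundant members were nearer to equality, with Uqcrq at 1462 and 1727 CPM, Cox4i1 at 713 and 826, mt-Nd1 at 1667 and 1806, Rps13 at 990.0 and 1192 and Rps20 at 1013 and 1119.

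Several of the lists that other cells or stages express most, and stress and antioxidant genes, were lower in aged spermatocyte-like cells. Free RNA of Leydig cells was lower there in CPM as well. Cyp17a1, Ptgds, Hsd3b6 and Star together were at 174 CPM in young and 57.7 CPM in aged spermatocyte-like cells. This is 2.52% and 3.17% of their level in the whole library, which was itself lower in the aged library (6925 and 1821 CPM). The median was -0.69 for steroidogenesis (1 of 17 higher, 10 lower), -1.28 for complement (0 of 11 higher, 7 lower), -0.83 for dissociation and stress (0 of 21 higher, 15 lower), -0.68 for Sertoli function (1 of 20 higher, 12 lower), -0.22 for antioxidant genes (1 of 29 higher, 11 lower), -1.09 for chromatin compaction (0 of 11 higher, 8 lower) and -0.29 for sperm motility (0 of 24 higher, 7 lower), each under the 1st percentile. Cyp17a1 was at 34.2 and 6.82 CPM and Prm1, a protamine of spermatids, at 141 and 51.1, whereas the abundant Ldhc, a sperm lactate dehydrogenase, was at 4827 and 4528. Clusters 1, 3, 5, 8 and 15 formed this class and held 384, 63, 65, 18 and 125 young and 747, 674, 454, 392 and 64 aged cells. In cluster 1 alone, chosen after the data were seen, the medians were 0.028 for meiotic recombination, 0.051 for DNA damage response, 0.25 for spermatogonial differentiation, -0.070 for oxidative phosphorylation, -0.29 for mitochondrially encoded genes and -0.057 for ribosomal proteins. The log2 ratio there was -0.033 for Fbxo3 and -8.02 for Aldh1l1. After subtraction of free RNA the medians were 0.44 for steroidogenesis, 0.23 for antioxidant genes and 3.64 for dissociation and stress.

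In round spermatid-like cells (544 young, 840 aged), the genes under the naming rule other than Aldh1l1 were at most 1.63-fold higher and 1.85-fold lower. Higher in the aged library were Tmem144 at 72.0 and 116 CPM (ratio 1.61, 1.49 to 1.73), Wbscr25 at 84.8 and 136, the RNA-binding protein gene Msi1 at 38.4 and 60.0, Fam227a at 39.1 and 60.7, Rnf168, a ubiquitin ligase of DNA repair, at 38.8 and 59.7, and the kinase pseudogene Stk-ps2 at 40.9 and 66.7, which can share reads with related genes. Lower were Osbpl1a at 92.3 and 49.8 CPM (1.85-fold, 1.69 to 2.03), Ide, the insulin-degrading protease gene, at 431 and 275, Tmem267 at 329 and 214, Pdcd10 at 62.8 and 43.3, and Mindy4, a deubiquitinase gene, at 67.5 and 48.1. Chromatin compaction genes, which replace histones in the sperm head, had a median of 0.09 (93.25th percentile), with 0 of 11 members at least 1.5-fold higher or lower. The remodeller gene Chd5 was at 225 and 303 CPM, Tnp1 at 499 and 538, and Prm2 at 151 and 102.

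Lists lay outside their random lists in 12 of 28 cases in round spermatid-like cells, 11 below and 1 above. Oxidative phosphorylation had a median of -0.17 (0 of 47 higher, 2 lower), mitochondrially encoded genes -0.50 (0 of 9 higher, 1 lower) and ribosomal proteins -0.11 (0 of 76 higher, 3 lower), with mt-Cytb at 384 and 269 CPM, Cox5a at 547 and 494 and Rps20 at 848 and 801. Spermatogonial differentiation was above its random lists at 0.40 (98.5th percentile, 0 of 7 higher, 1 lower), with Esx1 at 31.0 and 40.9 CPM and Dmrtb1 at 944 and 861. The rest lay lower, at -1.73 for steroidogenesis (0 of 16 higher, 11 lower), -0.44 for MHC class I (1 of 10 higher, 5 lower), -0.85 for complement (0 of 10 higher, 6 lower), -0.25 for extracellular matrix (4 of 32 higher, 13 lower), -0.22 for antioxidant genes (0 of 29 higher, 11 lower), -0.53 for dissociation and stress (1 of 21 higher, 10 lower), -0.50 for lysosome (0 of 18 higher, 8 lower) and -0.69 for resident macrophages (1 of 8 higher, 4 lower). Summed Leydig genes were at 265 CPM in young and 80.0 CPM in aged round spermatid-like cells, 3.83% and 4.40% of their level in the whole library. Outside the class mt-Cytb was at 4420 CPM in the young and 2736 CPM in the aged library, so its level in the class can include free RNA. With members of 1 count or more admitted, the resident macrophage median was 0.0016. Clusters 9, 11, 12 and 13 formed this class and held 144, 153, 100 and 147 young and 252, 230, 203 and 155 aged cells. The median share of mitochondrially encoded counts was highest in cluster 13 (0.362% young, 0.319% aged) and lowest in cluster 12 (0.0402% and 0.0259%). It was lower in the aged cells of each cluster. No values were taken within single clusters of this class, so the mix of clusters can hold part of its differences.

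In elongating spermatid-like cells (113 young, 158 aged), transcripts of proteins that pack sperm DNA were lower in the aged library over the class as a whole. Within each of its clusters, which were made from these same cells, these transcripts were close to equal. Prm1 was at 27842 and 19739 CPM (ratio 0.709, 0.700 to 0.718), Prm2, its fellow protamine, at 11873 and 8281 (0.697, 0.684 to 0.711), and the transition protein gene Tnp1 at 24767 and 18261 (0.737, 0.728 to 0.747). The chromatin compaction list had a median of -0.34 (0th percentile), with 0 of 10 members at least 1.5-fold higher or lower. The median gene of this class had a log2 ratio of 0.13, and relative to it the list stood at -0.48. The class is formed by cluster 17, led by Tnp2, Tnp1, Prm1 and Prm2, with 74 young and 72 aged cells, and cluster 19, with 39 and 86. Within cluster 17 alone and cluster 19 alone, alternatives chosen after the data were seen, the list median was -0.028 and 0.043, and the log2 ratio was -0.018 and 0.078 for Prm1, -0.079 and 0.0067 for Prm2 and -0.033 and 0.088 for Tnp1. In unnamed cluster 10 (75 young, 310 aged cells), led by Prm2 and Prm1 and with markers of both elongating spermatids and Sertoli cells, Prm1 was at 45631 and 44657 CPM, Prm2 at 20646 and 20369 and Tnp1 at 29676 and 26782. Higher were Col15a1, a collagen gene, at 32.3 and 68.2 CPM, the mucin gene Muc4 at 28.0 and 58.4, the phosphatase genes Ppm1f at 47.3 and 97.1 and Dusp21 at 37.5 and 74.9, the interferon gamma receptor gene Ifngr2 at 35.5 and 72.3, and the splicing factor gene Srsf6 at 29.6 and 59.4. Lower were Plekho1 at 61.1 and 33.6 CPM (1.82-fold, 1.35 to 2.47), the mitochondrial import gene Chchd4 at 50.1 and 30.0, Nemp2 at 68.2 and 43.9, the spliceosome gene Snrpd2 at 149 and 97.1, Aspscr1 at 93.5 and 61.5, and Cby3 at 84.8 and 56.8. Within clusters 17 and 19 alone the log2 ratio of Cby3 was 0.088 and 0.59 and that of Col15a1 0.37 and 0.51. The mix of these clusters differs between the libraries, so it can hold part of the ratios of the other named genes as well. Cluster 17 is led by the DNA-packing transcripts themselves. Near equality within the clusters therefore does not separate a difference between ages from one between clusters.

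All 8 of the 22 lists that lay outside their random lists in elongating spermatid-like cells lay below them. Beside chromatin compaction these were mitochondrially encoded genes at -1.08 (0 of 8 higher, 8 lower), with mt-Cytb at 463 and 209 CPM, ribosomal proteins at -0.14 (0 of 71 higher, 7 lower), with Rps20 at 1298 and 1084, oxidative phosphorylation at -0.0041 (2 of 46 higher, 5 lower), with Uqcrq at 665 and 717, and antioxidant genes at -0.46 (1 of 24 higher, 11 lower). Lists of other cell types were steroidogenesis at -1.02 (1 of 13 higher, 8 lower), Sertoli function at -0.81 (1 of 12 higher, 7 lower) and extracellular matrix at -0.32 (3 of 12 higher, 5 lower), which was 0.26 and inside its random lists with members of 1 count or more. Summed Leydig genes were at 247 CPM in young and 79.0 CPM in aged cells, which is 3.57% and 4.34% of their level in the whole library. The lipoprotein receptor gene Scarb1 of the steroidogenesis list was instead higher, at 117 and 185 CPM. Outside the class mt-Cytb was at 3281 CPM in the young and 2260 CPM in the aged library, so its level in the class can include free RNA. The mitochondrially encoded median was 0.19 in cluster 17 alone and -2.01 in cluster 19 alone, 0.17 with classes from the marker score of each cell and -0.089 with doublets kept. Relative to the median gene of the class, Uqcrq turned to -0.025.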

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

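All tests of the Leydig share in this part were chosen after the result was seen. Of the 6 unnamed clusters that the comparisons leave out, 3 hold cells of both libraries: cluster 10 (2.75% of young and 5.45% of aged cells), cluster 14 (2.38% and 3.34%) and cluster 20 (1.57% and 0.984%). The others hold cells of mostly 1 library. Cluster 21 held 88 cells, 3.22% of the young library, against 0 aged cells, which allows up to 0.0648% of that library. It carries genes of macrophages and microglia-like cells, with Adgre1 at 1805 CPM, Cd52 at 3484, Fcrls at 3486 and the chemokine genes Ccl3 at 2007 and Ccl4 at 2900, but little of the resident macrophage gene Mrc1 (10.1 CPM) or of the MHC class II gene H2-Aa (68.4 CPM). Cluster 6 held 506 cells, 8.89% of the aged library, against 0 young cells (up to 0.135%), scored highest for spermatocyte markers and had a median of 930 counts per cell, 0.0817 times that of its library. Its median share of mitochondrially encoded counts was 21.01%, against 0.588% in aged spermatocyte-like cells and a limit of 25% for kept cells, and mt-Co1 and mt-Nd5 are among its leading genes. A high share of such counts is often used as a mark of damaged cells. Cluster 7 held 424 cells, 7.45% of the aged library, against 2 young cells, between round and elongating spermatids, with a median of 1489.5 counts per aged cell. Both medians lie under the lowest total of any cell in the young file, 3215. Clusters 6, 7 and 21 were singled out by their share in 1 library. It was over 20 times that in the other library, and over 20 times the limit that 0 cells allow there. Whether they are cell types or properties of 1 library was not tested.

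The Leydig-like share was 39.9% in the young and 10.2% in the aged library. With the young file's lowest total applied to both libraries the ratio was 0.286 (0.256 to 0.319), and with every barcode kept it was 0.205 (0.184 to 0.227), so neither a lack of shallow young cells nor cells lost to the filters accounts for it. More germ cells in the aged suspension could lower the share without fewer Leydig cells, and the number of Leydig-like per macrophage-like cell was 0.767 times the young value (0.573 to 1.03) with cluster 21 among the macrophages and 0.240 (0.159 to 0.346) without it. That explanation stays open, since the result turns on cluster 21. A lower number of Leydig cells with age is an open and untested hypothesis.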

How the results depend on the processing

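The lower cell totals and the single clusters were chosen after the data were seen. Ratios of shares are aged over young and gene and list values are log2 ratios. Of 1134 values of genes under alternatives, 866 stayed within the interval of the reported value, 221 moved and 47 reversed. For lists these are 296, 57 and 19, and for shares 34, 32 and 11. The cause was not tested for any of them except where the text says otherwise. Of 50 lists described, 17 kept their side of their random lists (above, below or inside) in all alternatives run and 33 lost it in 1 or more. In Leydig-like cells steroidogenesis stayed inside (9 of 9 alternatives), and interferon response (9 of 9), dissociation and stress (9 of 9) and inflammatory genes (7 of 7) stayed above. Cell cycle stayed above in 6 of 9, MHC class I in 7 of 9 (down to the 29.0th percentile) and MHC class II in 5 of 7, and endothelial function in 8 of 9 (0.32 with members of 1 count or more). In spermatocyte-like cells mitochondrially encoded genes kept their side in 4 of 8, antioxidant in 5 of 8, Sertoli function in 6 of 8 and spermatogonial differentiation in 5 of 7. In spermatids those that kept it least were MHC class I (4 of 6, up to the 33.5th percentile) and chromatin compaction (4 of 6) in round, and extracellular matrix (3 of 6, up to 0.26 at the 66.8th percentile), mitochondrially encoded genes (5 of 8), chromatin compaction (6 of 8) and oxidative phosphorylation (6 of 8, up to the 14.8th percentile) in elongating spermatid-like cells.

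With every barcode kept the share ratio was 0.205 for Leydig-like (reported 0.256), 1.39 for spermatocyte-like (1.71), 0.620 for round spermatid-like (0.741) and 0.923 for elongating spermatid-like cells (0.671), and 0.896 for the elongating among spermatocytes and spermatids (0.551). With the stricter cell filter these were 0.286, 1.91, 0.879 and 1.20, and in elongating spermatid-like cells mt-Nd1 turned from -0.78 to 0.26 and Rps20 from -0.26 to 0.0034. With the young file's lowest total in both libraries the ratios were 0.286, 2.30, 1.04 and 1.09, fibroblast-like turned from 3.67 to 0.236, and chromatin compaction in elongating spermatid-like cells stood at -0.21 (reported -0.34). With that total scaled by depth the ratios were 0.299, 2.10, 0.946 and 1.12, and the elongating among germ cells 0.738.

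With doublets kept the spermatocyte-like ratio was 1.98, elongating 1.07 and elongating among germ cells 0.815. In Leydig-like cells Ldhc turned from -0.21 to 0.66, Odf2 from -0.33 to 0.20 and sperm motility from -0.34 to 0.045, and senescence and secreted factors stood at 1.86 (2.15). In elongating spermatid-like cells mt-Nd1 was 0.061 and chromatin compaction -0.21. Thinned before clustering, the ratios were 2.07 for spermatocyte-like, 0.944 for round and 1.93 for elongating spermatid-like cells. Leiden resolution 0.5 gave 1.23 and resolution 2 gave 1.15 for the elongating share. Macrophage-like cells, whose reported interval includes 1, moved to between 0.220 and 0.422 in 5 of 9 alternatives.

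With classes from each cell's marker score the round ratio was 0.915 and the elongating 1.73, the spermatocyte ratio among germ cells 1.27 (1.40) and the elongating 1.18. H2-Aa and MHC class II in Leydig-like cells turned from 2.39 to -0.075, senescence stood at 1.84, meiotic recombination in spermatocyte-like cells at 0.42 (0.36), and chromatin compaction at 0.16 in round (0.09) and -0.28 in elongating spermatid-like cells. In the latter Uqcrq turned from 0.11 to -0.0097, mt-Cytb from -1.14 to 0.086, mt-Nd1 to 0.33, mt-Nd4 from -1.24 to 0.14 and the mitochondrially encoded list from -1.08 to 0.17.

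In Leydig cluster 2 alone Ly6d was -0.34, B2m -0.14, Cd74 -0.075, H2-Aa -0.33, Cdkn1a -1.89, Gadd45a -0.79 and Mcm4 -0.72, and the lists were -0.22 for senescence, -0.12 for resident macrophage, 0.14 for Sertoli function, -0.27 for DNA damage response and -0.016 for cell cycle. There Cd74 and H2-Aa have 0 and Mcm4 1 aged count, too few to give a direction. In cluster 4 alone Hsd3b6 was 0.18, Igfbp7 0.47, Rpl10 0.14, Rplp0 0.15, Rps14 0.31, Rps21 0.20, Gas6 -0.81 and Gja1 -0.28, and the lists 0.18 for cholesterol synthesis, 1.67 for senescence, 0.30 for ribosomal proteins and -0.038 for cell cycle. The median gene lay at 0.14 and -0.16 in these clusters. In spermatocyte cluster 1 alone Fbxo3 was -0.033, Fdx1 -0.14, Cox4i1 -0.076, mt-Cytb -0.43, mt-Nd1 -0.0060, mt-Nd5 -0.23, Rpl10a -0.13, Rps20 -0.047 and Syce1 0.0081, and the lists -0.070 for oxidative phosphorylation, -0.29 for mitochondrially encoded genes, -0.057 for ribosomal proteins and 0.028 for meiotic recombination. In elongating spermatid cluster 17 alone Cby3 was 0.088, Uqcrq -0.046, mt-Cytb 0.19, mt-Nd1 0.49 and mt-Nd4 0.0082, and the lists 0.19 for mitochondrially encoded genes and -0.028 for chromatin compaction. In cluster 19 alone Cby3 was 0.59, Rps20 0.12, Prm1 0.078, Prm2 0.0067, Tnp1 0.088 and chromatin compaction 0.043.

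With free RNA subtracted from spermatocyte-like cells Gapdhs turned from -0.85 to 5.16, steroidogenesis to 0.44, antioxidant to 0.23 and dissociation and stress to 3.64, where the subtraction takes levels to 0 by its construction. With members of 50 or more counts senescence in Leydig-like cells stood at 1.04, and with members of 1 count or more the resident macrophage list in round spermatid-like cells turned from -0.69 to 0.0016. Centred on the median gene, Uqcrq in elongating spermatid-like cells was -0.025 and chromatin compaction -0.48, and as a mean over cells mt-Nd1 was 0.29.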

Other observations

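Of the tests in this part, those of free RNA and of gene loss for Aldh1l1 and of macrophage RNA for the Leydig chemokines were chosen after the result was seen. So were the interval applied to the share of Cxcl1 in few cells, the test of the list without such cells and the share of Ccl2 in few cells. Macrophage-like cells (40 young, 89 aged) were too few for the comparisons. Their MHC class II genes, which present antigen to T cells, had a median log2 ratio of 0.80 (99.0th percentile, 4 of 7 at least 1.5-fold higher, 0 lower), with H2-Aa at 2609 and 5544 CPM in the young and aged library and Cd74 at 3029 and 5535. Genes of resident macrophages had a median of -0.72 (0 of 12 higher, 9 lower), with the scavenger receptor gene Stab1 at 1122 and 424 CPM, Cbr2 at 3559 and 2124 and F13a1 at 2802 and 1599. Interferon response genes had a median of -1.16 (1 of 15 higher, 11 lower), with Gbp2 at 658 and 77.1 CPM. The inflammatory list had a median of 1.21 (7 of 13 higher, 1 lower), with Ccl2 at 862 and 1999 CPM and Cxcl2 at 105 and 1219 (ratio 11.6, 7.28 to 19.6). RNA of other cells differs there too: meiotic recombination genes of germ cells had a median of 2.55 (6 of 6 higher), and the summed Leydig genes Cyp17a1, Ptgds, Hsd3b6 and Star were at 304 and 482 CPM, 4.39% and 26.5% of their level in the whole library. DNA damage response (1.64, 8 of 9 higher, 0 lower) and cell cycle genes (1.49, 4 of 7 higher, 0 lower) were also above their random lists. The 88 young cells of cluster 21, which hold Ccl3 and Ccl4, lie outside this class, and Cd74, H2-Aa and F13a1 are among the genes that lead its cluster.

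Fibroblast-like cells (17 young, 130 aged) had a median of -0.49 for extracellular matrix genes (0th percentile, 1 of 30 higher, 13 lower). The matrix glycoprotein gene Fn1 was at 246 and 4.96 CPM and Sparc at 4709.8 and 3182, resting on 19 young and 1 aged count for Fn1, while the collagen gene Col15a1 was at 51.8 and 338 and the proteoglycan gene Dcn at 10597 and 12242. Macrophage transcripts in the same cells were also lower in the aged library, with the resident macrophage list at -3.22 (0 of 5 higher, 3 lower), C1qb at 246 and 4.96 CPM, Lyz2 at 181 and 14.9 and Cbr2 at 207 and 9.93. Dissociation and stress genes had a median of 0.40 (100th percentile, 7 of 22 higher, 1 lower), with Fos at 5279 and 7188 CPM.

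Aldh1l1 was near absent from germ cells of the aged library. Reads given to a neighbouring gene would raise 1 nearby, but the largest gain among 12 genes within 100 kb was 0.791 CPM. Reads that a pipeline counts for no gene would raise no neighbour, and the sources differ on the pipeline. A difference in processing that left the whole gene uncounted would have removed it from aged Leydig-like cells too, which had 1188 counts of it. A difference in processing that affects only part of its reads stays open. Free RNA would leave at most a few percent of the Leydig level in young spermatocyte-like cells, where the level was 20.7%, and loss of the gene would lower it in Leydig-like cells, where the ratio was 0.989 (0.925 to 1.06). A difference in how germ cells use the gene, between ages or between the strains or animals of the libraries, may account for the pattern and was not tested.

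Chemokine and secreted factor genes were higher in aged Leydig-like cells. Macrophage RNA would need to make up 5.01% of the Leydig RNA to bring the Ccl2 level, and macrophage genes (C1qa, C1qb, C1qc, Lyz2 and Csf1r) reached 0.0542 times the level that share would bring, so it does not account for Ccl2. The test does not cover the MHC class II genes in Leydig-like cells, where Cd74 was at 13.9 CPM against 5535 in macrophage-like cells and Lyz2 was higher too, so macrophage RNA stays open for them. A stronger response to dissociation in the aged suspension could raise such genes in other cell types too. The dissociation list lay at the 61.3th percentile in macrophage-like cells (median -0.11), which leaves it open, and at the 100th in fibroblast-like and Leydig-like cells. In germ cells its median was -0.83 in spermatocyte-like, -0.53 in round spermatid-like (both 0th percentile) and -0.087 in elongating spermatid-like cells (7.64th). Free RNA of Leydig cells was lower there in CPM as well, so these values do not settle it. The 30 aged Leydig-like cells with the most Cxcl1 held 24.9% of its counts (23.6 to 26.3), at the bound of 25% set beforehand within its interval. Without the 30 cells that hold most of the senescence and secreted factors list, its median was 2.12 (1.63 to 2.26). Those cells alone do not account for the list median. Abundant members weigh most in picking such cells, with Igfbp7 at 1728 and Cxcl1 at 1456 CPM in the aged library. The test therefore cannot exclude a few cells as the source of members at low counts. In cluster 2 alone, with 57 aged cells, the list median was -0.22, and in cluster 4 alone, with 524, it was 1.67. For Ccl2 itself the 30 cells with the most held 67.7% of the counts (61.9 to 73.2), past the bound of 50% set for Cxcl1, so a few cells fit as the source of most of its counts. Without its own top 30 cells Cxcl1 was at 1227 CPM, 3.14-fold the young level (2.99 to 3.30), and Ccl2 at 36.6 CPM, 18.2-fold (10.6 to 33.0), so those cells do not hold all of its difference. After thinning to 2000 counts, Ccl2 had a count in 0.367% of young and 10.6% of aged Leydig-like cells, and Cxcl1 in 33.3% and 65.2%, against 0.153% and 0.180% of spermatocyte-like cells for Cxcl1. Age stays open as an untested explanation.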
